A study of Mus musculus with 8 samples.

How the data were processed

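RNA was measured in macrophages sorted from the livers of wild-type BALB/c mice, in 4 samples from vehicle-treated and 4 from CCl4-treated mice. Per the labels' protocols, perfused livers were digested with collagenase, hepatocytes were spun out at low speed, and live cells positive for CD45 (the pan-leukocyte surface protein) and F4/80 (a macrophage surface protein, encoded by Adgre1) were sorted. The series' design text adds that the sorted cells were negative for CD31, the endothelial protein encoded by Pecam1. Little RNA was used per sample, amplified with the SMART-Seq HT kit, and libraries were made with NEBNext Ultra II. Per the labels' protocols no step is named that marks the strand, so reads of overlapping or antisense genes cannot be told apart. Groups came from the treatment label of each sample. Nothing in the labels says that each library is a separate mouse, so p-values measure the spread between these samples, which may be partly technical. The dose and duration of CCl4 are not given in the sources used here.

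Each sample had a table of kallisto estimated counts and TPM per transcript, deposited by the authors and not normalized between samples in the case of the estimated counts. Per the submitters' processing notes, kallisto, edgeR and limma were used and the build was mm10. Their versions, the transcript release and the role of each tool are not given in the sources used here. The series also had a table of FPKM per gene, deposited by the authors. How that FPKM table was made is not given in the sources used here, and its columns summed to between 81142 and 113842. The TPM values deposited by the authors are transcript abundances scaled to a fixed total within a sample. They entered only the alternatives of length-scaled TPM counts and of a removed length trend, the latter through the ratio of counts to TPM. Deposited transcript lengths entered only the length-scaled TPM counts.

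Transcripts were assigned to genes with the GENCODE M21 annotation of mm10 by their identifiers without the version suffix. Of 117494 transcripts in each file, 116405 matched, but only 13 matched with the version suffix as well, so the authors' transcript models can differ from those of M21 at any gene. The 1089 unmatched transcripts held between 0.29% and 0.313% of the estimated counts of a library and were left out. Coordinates are those of M21, counted from 1. Estimated counts were summed per gene over 35906 genes and rounded to whole numbers. kallisto shares reads between similar transcripts, so values for members of near-identical families, such as the major urinary protein, haemoglobin alpha and immunoglobulin genes and the Cd209 cluster, are uncertain. The FPKM table had 29956 named genes, of which 28221 shared a symbol with the count table. Its 1 unnamed line, with 0.0156% to 0.0369% of a column, was left out.

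Library totals ran from 19489104 to 26196063 estimated counts. No 2 libraries of a group were near-duplicates: the mean chi-square per gene between libraries of 1 group was 30.02 or more, where sampling noise alone gives about 1. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15212 genes and set aside 20694. CCl4 was compared with vehicle by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization and group as the sole term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-normalized CPM, except that values summed over a list or over receptor genes are CPM of the library total without TMM factors. SE of a log2 fold change was taken as its size divided by the square root of the test's F statistic. In simulated counts with 200 of 14926 genes changed, the test recovered 72% of genes changed by a log2 of 1 and 96% of those changed by a log2 of 2, and 4% of its calls were false. The changed genes were drawn above a minimum level, with as many raised as lowered and no library set apart. These rates may therefore not hold for low genes or for libraries that differ in background. The same simulation gave DESeq2 15% false calls.

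There were 39 gene lists for macrophage states, functions, other liver cells and sample quality, of which 38 had the 3 tested members needed for a set test. The lists, the test, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), which compares a list with the other genes, at a preset correlation of 0.01 between genes and again with that correlation estimated. They were also tested with fry, which asks whether the genes of a list move on balance in 1 direction. In simulated lists with no change, 3% fell under p = 0.05 with the preset correlation, 0% with an estimated one and 6% by fry. Genes varied independently in these simulated counts, so the rates do not cover lists whose genes move together. The estimated correlation was 0.571 in the Kupffer cell list and 0.852 in the mitochondrially encoded list. Single values per sample were compared by exact permutation tests over all 70 assignments of the 8 libraries, two-sided, for which the smallest possible p is 0.029. With all 4 libraries on either side of a gap in each group, chance alone sets 2.86% of genes fully apart.

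Named genes were of 3 kinds. The first were the 12 highest and 12 lowest log2 fold changes among protein-coding genes past the threshold with a mean of at least 10 CPM and all CCl4 libraries on 1 side of all vehicle libraries. The second were up to 4 members with the smallest p of each described list. The third were 27 genes chosen for the tissue and gate whatever their values, of which the X-inactivation gene is not analysed here. Some genes that the rule names are not reported here. A gene outside these is named as chosen after its values were seen. Alternatives covered 3 other scalings, 2 other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, length-scaled TPM, the FPKM table with limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 4 libraries, the first of these without a filter, removal of mitochondrial and ribosomal protein genes, the replicate number as a block, and leaving out each library in turn. Another 4 were added after seeing the data: leaving out vehicle 2 and CCl4 4 together, leaving out the 50 most abundant genes, removing a trend with transcript length, and a covariate for the level of olfactory and vomeronasal receptor genes. Nuclear copies of mitochondrial genes were found with blastn 2.17.0 (at least 90% identity over at least 100 bases), which gave 17 genes. A floor of 3 counts over a group stands for a gene at 0, and floors cover counting error only.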

Results

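The series asked how the transcriptome of liver macrophages differs in liver fibrosis. Carbon tetrachloride (CCl4) is a liver toxin that injures hepatocytes and, when given repeatedly, is a standard way to produce fibrosis in mice. Macrophages sorted from digested livers as CD45-positive, F4/80-positive, CD31-negative cells were profiled by RNA sequencing in 4 samples from CCl4-treated and 4 from vehicle-treated BALB/c mice. Total estimated counts were 25816812, 19686629, 23992855 and 23497101 in vehicle 1 to 4 and 23602507, 25939492, 26196063 and 19489104 in CCl4 1 to 4, with no detectable difference between groups (exact permutation p = 0.771). Levels are TMM-normalized CPM (counts scaled to library size; sums over genes without TMM factors), given as mean ± SD with n = 4 per group, and fold changes are CCl4 over vehicle.

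Liver macrophages of CCl4-treated mice had lower levels of resident Kupffer cell transcripts and higher levels of those known from lipid-handling, scar-associated and monocyte-derived macrophages. Gpnmb, a lysosomal membrane glycoprotein of lipid-laden macrophages, rose from 22.8 ± 22.9 to 7102 ± 2699 CPM, and the C-type lectin Cd209g fell from 170.9 ± 27 to 4.09 ± 1.45 CPM. Of 15212 genes tested, 1358 were higher and 953 lower in CCl4 by edgeR's quasi-likelihood test. Among these, 789 rose and 534 fell by a log2 of 1 or more. The libraries of the groups were fully apart for 2166 of the 2311 called genes and for 22.5% of all genes tested, where chance gives 2.86%. The direction of the calls depended on the scaling. With TMM 58.8% of calls were higher, against 43.1% (1082 higher, 1431 lower) with library size only and 47.5% (1226 higher, 1356 lower) with upper-quartile scaling, while the median log2 fold change of all tested genes went from -0.029 to -0.155 and -0.119. Without CCl4 1, 578 genes were lower.

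The first principal component held 44.5% of the variance and separated the groups, with vehicle libraries between -76.7 and -25 and CCl4 libraries between 4.5 and 73. The second component (23.6%) set CCl4 4, at -73.9, and vehicle 2, at -31, apart from most others, although CCl4 1 lay at -25.5. These 2 libraries had the lowest totals and the most genes detected, 16456 and 16098 against 14169 to 15312 in the other 6. They also had the most counts from olfactory and vomeronasal receptor genes, chemosensory genes with no known role in liver macrophages, at 2979 and 3029 CPM summed over 1465 genes against 598 to 1509. Leaving both out gave 1653 higher and 1163 lower genes.

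**Figure D1:**
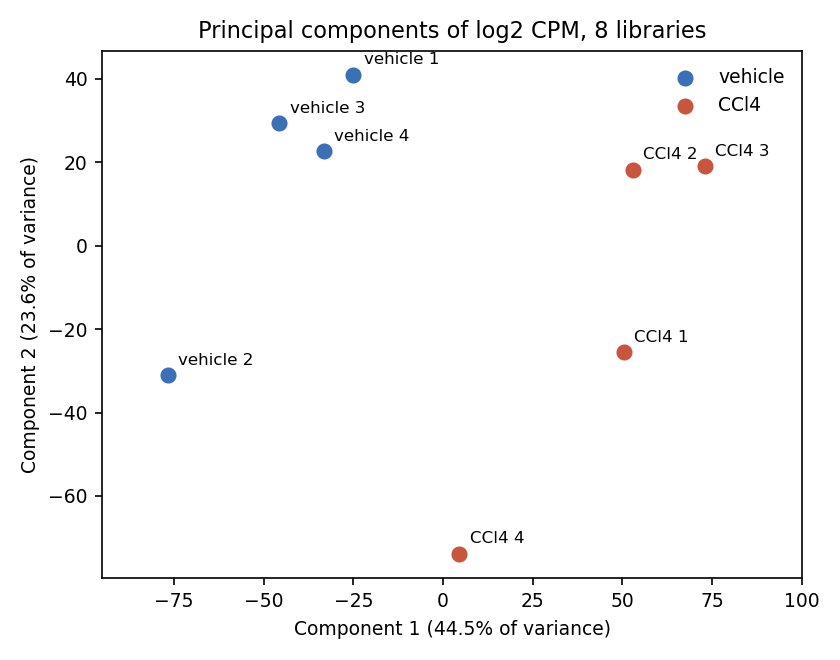
Principal components of log2 CPM of the tested genes. Each point is a library, with component 1 (44.5% of variance) on the horizontal and component 2 (23.6%) on the vertical axis. All CCl4 libraries lie right of all vehicle libraries, and CCl4 4 lies lowest at -73.9.

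Resident Kupffer cell genes fell. Of 24 tested members of the Kupffer cell list, 22 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 fold change of -1.49. Of these 24 genes 10 are in another list too, and 13 of 19 sinusoidal endothelial genes fell in the same libraries (median -1.05). Clec4f, a C-type lectin of Kupffer cells, fell from 11870 ± 2694 to 3598 ± 1094 CPM (log2 fold change -1.72, SE 0.26, edgeR adjusted p = 0.000977; chromosome 6, 83644542 to 83656187). Timd4, the phosphatidylserine receptor of embryonically seeded macrophages, fell from 585.7 ± 54.2 to 107.0 ± 34.2 CPM (-2.45, SE 0.23, edgeR adjusted p = 5.44e-05; chromosome 11, 46810800 to 46844332). The haemoglobin scavenger receptor Cd163 had a log2 fold change of -3.26 (SE 0.35), the lectin-pathway ficolin Fcna one of -2.86 (SE 0.18), and the apoptosis inhibitor Cd5l one of -1.26 (SE 0.25). Cdh5 (-2.31, SE 0.17), which is in the endothelial list as well, and Pcolce2 (-2.49, SE 0.21) also fell. The complement receptor Vsig4 went from 2749 ± 254 to 1577 ± 451 CPM (-0.80, SE 0.21, edgeR adjusted p = 0.0212). That call ended without vehicle 1, 3 or 4 or CCl4 1 or 3 (edgeR adjusted p of 0.051, 0.065, 0.055, 0.068 and 0.052). The scavenger receptor Marco, at 65.4 ± 15.7 and 45.5 ± 16.4 CPM, did not pass the test (edgeR adjusted p = 0.194). As a set the list passed camera with the preset correlation (adjusted p = 1.8e-16), gave adjusted p = 0.42 with an estimated correlation and 0.0034 by fry.

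Genes of lipid- and scar-associated macrophages rose. Of 22 tested members 18 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 2.20, and 8 of the 22 are in another list too. Gpnmb had a log2 fold change of 8.28 (SE 0.75, edgeR adjusted p = 4.63e-05; chromosome 6, 49036546 to 49070929), with vehicle libraries between 8.33 and 56.5 CPM and CCl4 libraries between 3915 and 9522. Trem2, a lipid-sensing receptor, rose from 53.5 ± 8.3 to 552.5 ± 100.2 CPM (3.37, SE 0.19, edgeR adjusted p = 2.63e-06; chromosome 17, 48346401 to 48354147). Fabp5, a fatty-acid binding protein, rose from 2.44 ± 0.74 to 103.8 ± 20.9 CPM (5.41, SE 0.26), and Atp6v0d2, a subunit of the proton pump of lysosomes and osteoclasts, from 4.88 ± 1.53 to 395.7 ± 147.0 CPM (6.34, SE 0.36). Spp1, which encodes osteopontin, rose from 96.2 ± 88.6 to 2200 ± 809 CPM, the tetraspanin Cd9 from 68.2 ± 29.2 to 451.1 ± 186.6 CPM, and galectin-3 (Lgals3) from 1030 ± 167 to 2908 ± 1075 CPM. The cathepsin Ctsd rose from 4248 ± 803 to 25270 ± 4630 CPM. The set passed camera with the preset correlation (adjusted p = 1.7e-18), with adjusted p = 0.42 with an estimated correlation and 0.00054 by fry.

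**Figure D2:**
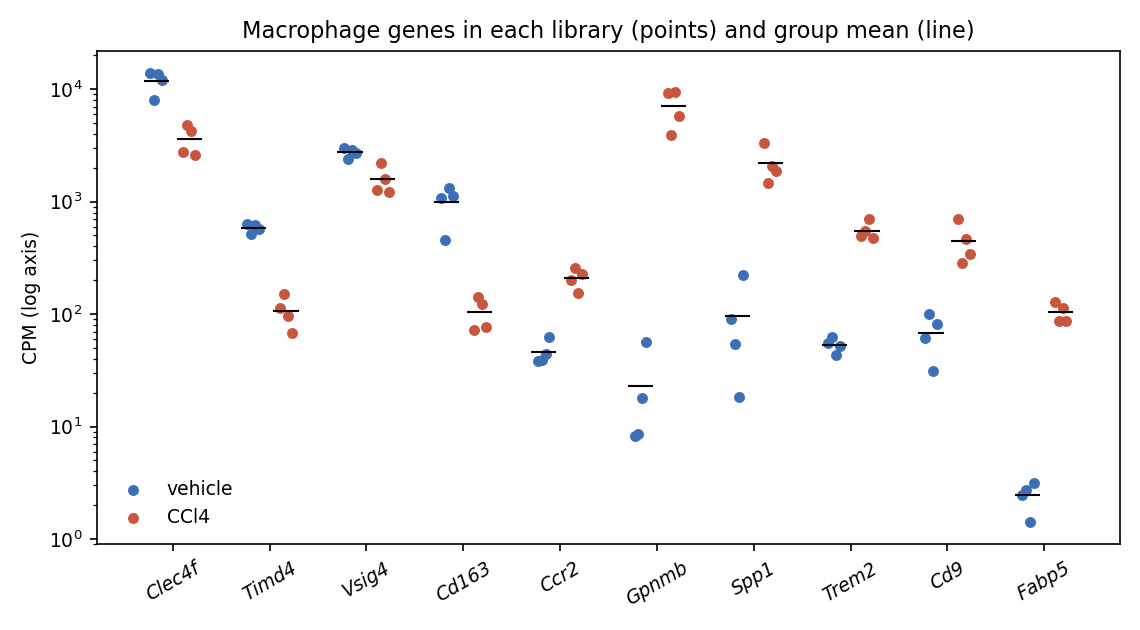
Levels of 10 macrophage genes in CPM on a log axis. Points are libraries, blue for vehicle and red for CCl4, and lines are group means. The groups do not overlap for any of these genes; Gpnmb is between 8.33 and 56.5 CPM in vehicle and between 3915 and 9522 in CCl4.

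Monocyte-derived macrophage genes rose on balance. Of 19 tested members 10 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 1.55, and 6 of the 19 are in another list too. The chemokine receptor Ccr2, which brings monocytes out of the bone marrow, rose from 46.3 ± 11.3 to 209.4 ± 44.3 CPM (2.18, SE 0.21, edgeR adjusted p = 7.33e-05), the integrin Itgax from 17.7 ± 3.2 to 218.1 ± 118.4 CPM, and the chitinase-like protein Chil3 from 1.54 ± 0.91 to 46.8 ± 31.9 CPM. The fractalkine receptor Cx3cr1 rose by 1.05 (SE 0.22) on the log2 scale. Ifitm3, the most abundant member of the list, fell from 606.7 ± 131.6 to 332.5 ± 42.6 CPM (-0.87, edgeR adjusted p = 0.00691). The next, Fn1, was at 349.2 ± 178.6 and 558.7 ± 142.8 CPM and did not pass (edgeR adjusted p = 0.186). Ifitm3 and Fn1 were chosen after their values were seen. Ly6c2, a surface marker of inflammatory monocytes, was low, at 0.93 ± 0.58 and 2.95 ± 2.01 CPM, and did not pass (edgeR adjusted p = 0.0658), but passed without vehicle 2 (edgeR adjusted p = 0.026). For this set camera gave adjusted p = 5.6e-07 with the preset correlation and adjusted p = 0.42 with an estimated correlation, and fry 0.0078. Neutrophil genes, described with other cell types, rose beside these.

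Of the 3 genes of the sort gate, Pecam1 fell and the others did not pass the test. Adgre1 was at 1272 ± 210 and 1187 ± 166 CPM and Ptprc, which encodes CD45, at 512.3 ± 78.0 and 623.4 ± 73.8 CPM; neither passed (edgeR adjusted p = 0.768 and 0.289). Pecam1 fell from 73.8 ± 21.3 to 27.4 ± 2.9 CPM (-1.43, SE 0.21, edgeR adjusted p = 0.00096) (1 of 3 gate genes, also adjusted over the list alone). Among 12 pan-macrophage genes 2 rose and 1 fell (3 and 1 adjusted over the list alone). Lysozyme (Lyz2) rose from 16440 ± 2578 to 47030 ± 6266 CPM and Aif1 fell from 563.7 ± 150.3 to 277.9 ± 69.1 CPM. The other rise was Cd14 (0.90, SE 0.26), whose call ended without vehicle 2, 3 or 4 or CCl4 1 or 3 (edgeR adjusted p of 0.062, 0.11, 0.093, 0.084 and 0.09). The list median was 0.12 and -0.02 with library size only. Of 12 genes of capsular and Cx3cr1-expressing macrophages 3 rose and 2 fell (4 and 2 adjusted over the list alone), and the median (0.43), mean (-0.42) and camera direction (up) differed in sign. Cd209g (-5.38, SE 0.26) and Cd209f (-4.68, SE 0.30) fell while Cd207 (1.05, SE 0.17) and Cd52 (1.60, SE 0.25) rose.

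Further genes with the largest changes belonged to several classes. Syndecan Sdc1 rose from 2.10 ± 0.85 to 164.7 ± 118.9 CPM, the vesicle protein Syngr1 from 4.15 ± 0.66 to 74.4 ± 12.1, the TGF-beta family member Gdf3 from 1.81 ± 0.77 to 39.5 ± 10.4, Cd200 from 2.53 ± 1.26 to 54.2 ± 35.8, and the peptidase Anpep from 3.81 ± 1.05 to 65.4 ± 22.4. The Notch target Hes1 fell from 83.3 ± 35.3 to 12.7 ± 5.7 CPM, the adenylate cyclase Adcy4 from 110.9 ± 41.1 to 15.9 ± 4.6, Sectm1a from 26.3 ± 7.8 to 2.63 ± 0.99, and Gpm6b from 31.3 ± 1.1 to 4.02 ± 0.51. All 9 passed the edgeR test, with all CCl4 libraries on 1 side of all vehicle libraries.

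Matrix-degrading genes rose, and the profibrotic ligands Tgfb1 and Pdgfb did not pass the test. Of 18 matrix degradation genes 10 rose and 0 fell (12 and 0 adjusted over the list alone; median 1.14), and 5 of the 18 are in another list. Genes of other cells rose in the same libraries: 9 of 16 neutrophil genes, among them Mmp8, which is in both lists, 8 of 12 mesothelial genes in a list made after the values were seen (median 2.89), and Col1a1 (2.54). The macrophage elastase Mmp12 rose from 456.3 ± 205.8 to 3623 ± 2160 CPM (2.99, SE 0.48), the metalloprotease Adam8 from 33.2 ± 15.9 to 476.0 ± 161.0 CPM, the membrane-bound Mmp14 from 19.3 ± 5.9 to 93.7 ± 20.7 CPM, and the inhibitor Timp1, also in the stellate list and low, from 0.27 ± 0.13 to 4.13 ± 0.95 CPM. The collagenase Mmp13 had a log2 fold change of 0.63 (SE 0.39, edgeR adjusted p = 0.334). This set passed camera (adjusted p = 3.4e-08 with the preset correlation and adjusted p = 0.42 with an estimated correlation) and fry (0.0035). Of 22 profibrotic and growth factor genes 8 rose and 4 fell (9 and 5 adjusted over the list alone). Arginase Arg1 (3.80, SE 0.43), Vegfa (3.15, SE 0.36) and Thbs1 (2.66, SE 0.34) rose and Hbegf fell (-2.14, SE 0.21). Tgfb1 was at 11.2 ± 1.5 and 8.27 ± 1.16 CPM and Pdgfb at 16.3 ± 2.3 and 18.5 ± 4.1 CPM (edgeR adjusted p = 0.127 and 0.599). The Tgfb1 difference passed with edgeR on length-scaled TPM counts, and its sign varied among the settings tried, from -0.79 to 0.20. As a set this list missed the threshold of camera (adjusted p = 0.086), which it passed without vehicle 4 (0.036) and in 5 other settings, and it passed fry (adjusted p = 0.026).

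Lipid and lysosome genes moved in several ways. Of 21 cholesterol synthesis genes 11 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.81), among them Msmo1 (1.41, SE 0.12), Hmgcs1 (1.17, SE 0.15), Sc5d (1.10, SE 0.15) and Idi1 (1.14, SE 0.17). Camera gave adjusted p = 3.2e-09 with the preset correlation and adjusted p = 0.42 with an estimated correlation, and fry 0.0035. Of 28 lysosome genes 11 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.53). Prosaposin (Psap) rose from 1141 ± 341 to 9000 ± 3235 CPM and Ctsl from 306.4 ± 21.8 to 976.7 ± 255.2 CPM. Here adjusted p was 3.6e-07 with the preset correlation and adjusted p = 0.59 with an estimated correlation, and 0.013 by fry. Among 15 genes of LXR signalling and cholesterol efflux 4 rose and 3 fell (5 and 3 adjusted over the list alone): the cholesterol transporter Npc1 (0.88, SE 0.14) and Apoc2 (1.37, SE 0.23) rose, and Apoc1 (-1.07, SE 0.20) and Nr1h3, which encodes the receptor LXR-alpha (-0.97, SE 0.19), fell. Of 19 fatty acid oxidation genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), the largest change being the transcription factor Pparg (1.23, SE 0.21). The calls of Acadl and Eci1 each ended on leaving out any of 6 single libraries (edgeR adjusted p up to 0.12 and 0.076), and the median of 0.12 became -0.02 with library size only. Of 25 phagocytosis receptors 8 rose and 3 fell (11 and 3 adjusted over the list alone), with Cd36 (2.18, SE 0.21), Olr1 (3.14, SE 0.34) and Clec7a (1.77, SE 0.20) higher and Timd4 lower. That set passed camera (adjusted p = 0.022 with the preset correlation, adjusted p = 0.78 with an estimated correlation) but not without vehicle 2 (0.13), CCl4 2 (0.066) or CCl4 3 (0.06), and not by fry (0.055).

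**Figure D3:**
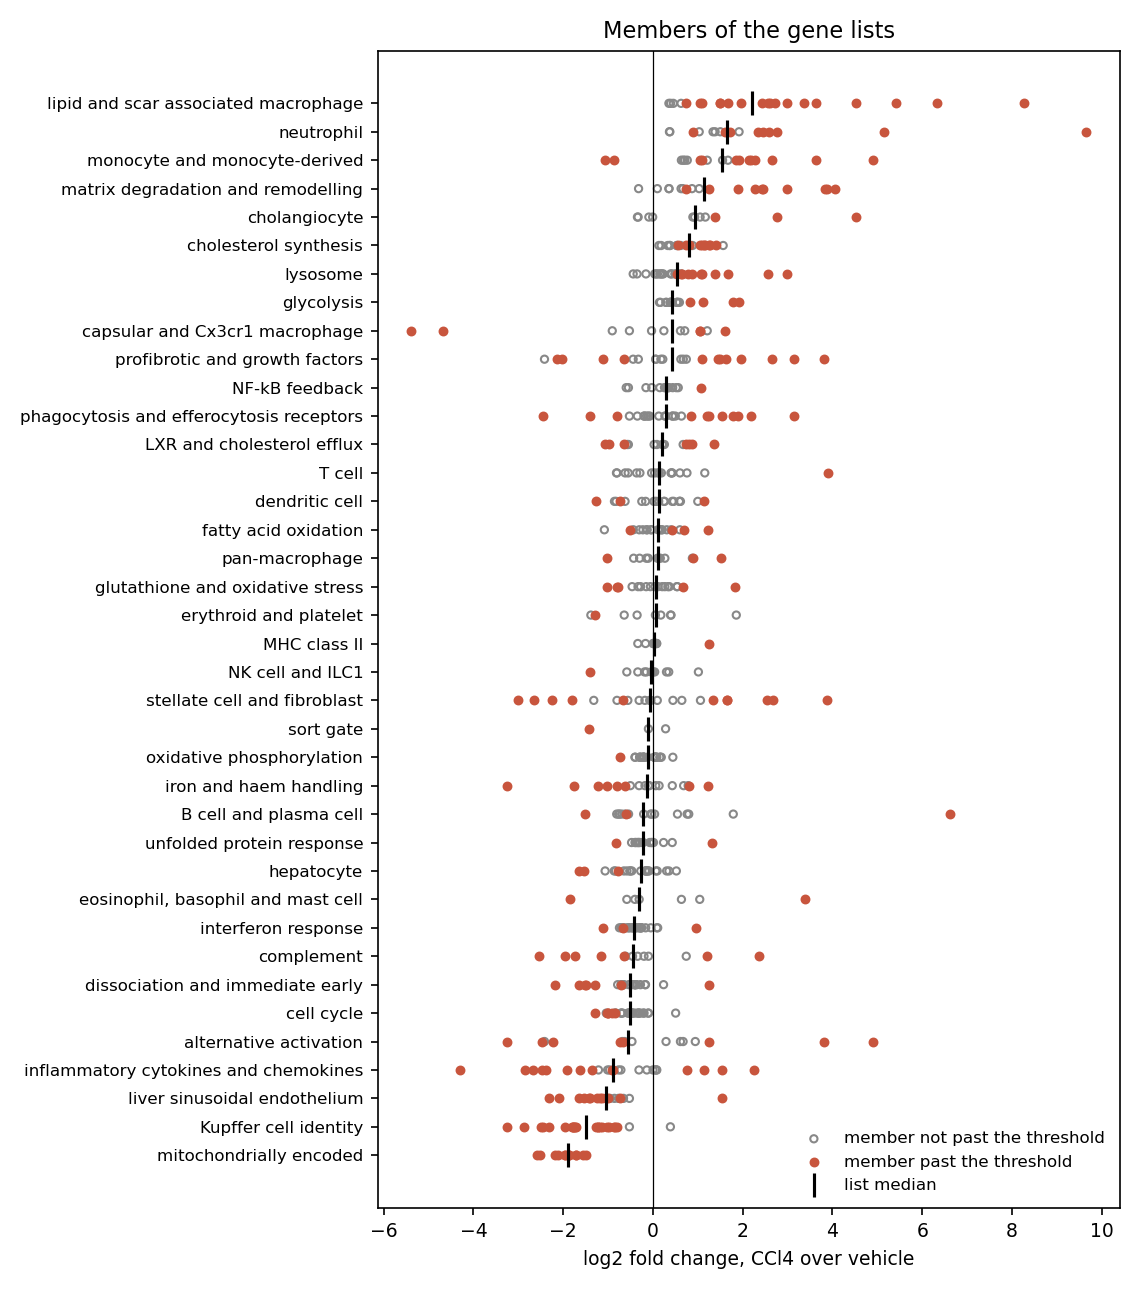
Log2 fold changes (CCl4 over vehicle) of the tested members of 38 gene lists. Each circle is a gene, filled where it passed the edgeR threshold of 0.05, and the vertical bar is the list median. Medians run from -1.89 for mitochondrially encoded genes to 2.20 for lipid and scar associated macrophage genes.

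Mitochondrially encoded genes fell. All 13 mitochondrially encoded genes tested fell (13 adjusted over the list alone; median -1.89), among them mt-Cytb (-1.97, SE 0.28), mt-Nd1 (-2.12, SE 0.31), mt-Co1 (-1.71, SE 0.27) and mt-Nd2 (-2.52, SE 0.40). Mitochondrial transcripts were 3.97, 5.31, 3.16 and 1.91% of the counts of vehicle 1 to 4 and 0.93, 1.16, 0.76 and 0.90% of those of CCl4 1 to 4 (exact permutation p = 0.0286, adjusted to 0.0857 over 18 sample-level values). The set passed camera (adjusted p = 1.3e-09 with the preset correlation, adjusted p = 0.42 with an estimated correlation) and fry (0.011). The mitochondrial share is also a sign of RNA and cell quality, and it differed between the groups beside every list called here. Of 23 nuclear-encoded oxidative phosphorylation genes 0 rose and 1 fell, Cox5a (0 and 1 adjusted over the list alone; median -0.12, from -0.27 to 0.06 over the settings). Of 17 glycolysis genes 4 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.43): the glucose transporter Slc2a1 (1.79, SE 0.23), the lactate exporter Slc16a3 (1.91, SE 0.38), Pgam1 (1.13, SE 0.14) and Ldha (0.82, SE 0.16). Camera gave adjusted p = 1.2e-05 with the preset correlation and adjusted p = 0.5 with an estimated correlation, and fry 0.013.

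**Figure D4:**
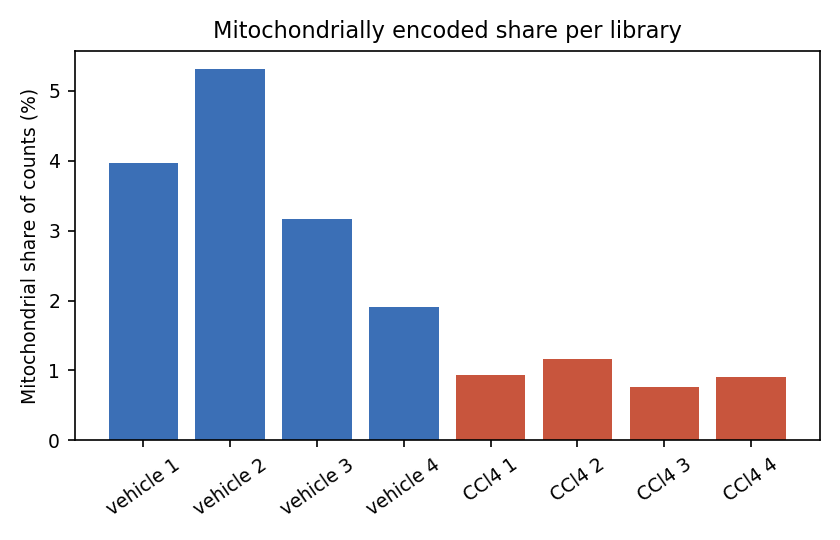
Share of counts from mitochondrially encoded genes in each library, in percent. Vehicle libraries (blue) lie between 1.91 and 5.31%, CCl4 libraries (red) between 0.76 and 1.16%.

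Iron and stress genes were mixed. Of 18 iron and haem genes 2 rose and 6 fell (3 and 7 adjusted over the list alone). Cd163, the transcription factor Spic (-1.75, SE 0.23) and the biliverdin reductase Blvrb (-0.80, SE 0.16) fell, and the ferrireductase Steap3 rose (1.23, SE 0.25). Of 18 glutathione and oxidative stress genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with the cystine transporter Slc7a11 higher (1.83, SE 0.39) and Gclm (-0.78, SE 0.15), Hmox1 (-1.03, SE 0.23) and Sod1 (-0.79, SE 0.18) lower. This list's median (0.08) and mean (0.06) were above 0 and its camera direction down, and the median was -0.06 with library size only and -0.02 with upper-quartile scaling. Of 17 unfolded protein response genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), Asns (1.32) and Herpud1 (-0.83). None of these 3 sets passed camera (adjusted p = 0.2, 0.92 and 0.18).

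Inflammatory cytokine genes fell more often than they rose. Of 25 tested 10 fell and 4 rose (11 and 4 adjusted over the list alone; median -0.88). Il6 fell from 192.6 ± 41.0 to 26.7 ± 5.9 CPM (-2.85, SE 0.21, edgeR adjusted p = 1.65e-05), the B cell attractant Cxcl13 from 135.1 ± 49.6 to 6.84 ± 3.05 CPM, the eosinophil attractant Ccl24 from 556.9 ± 49.2 to 100.6 ± 19.7 CPM, Tnf from 200.1 ± 35.4 to 65.1 ± 19.4 CPM, the monocyte attractant Ccl2 from 364.7 ± 184.4 to 70.3 ± 23.7 CPM and Ccl12 from 18.5 ± 8.5 to 2.87 ± 1.64 CPM. Ccl9 rose from 64.4 ± 22.8 to 307.0 ± 81.7 CPM. Il1b was at 2563 ± 940 and 2335 ± 500 CPM (edgeR adjusted p = 0.786). The set passed camera (adjusted p = 0.0023 with the preset correlation, adjusted p = 0.75 with an estimated correlation), but not without vehicle 2 and CCl4 4 together (0.08), and its fry adjusted p of 0.05 was just under the threshold before rounding. Of 26 interferon response genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; median -0.42), with Oas3 higher (0.96, SE 0.20) and Gbp3 lower (-1.12, SE 0.21). The interferon set (camera adjusted p = 0.0051 with the preset correlation, adjusted p = 0.7 with an estimated correlation) no longer passed without CCl4 4 (0.072) and did not pass fry (0.13). Of 14 NF-kB feedback genes 1 rose, Zc3h12a, and 0 fell (1 and 0 adjusted over the list alone), and the set missed the threshold (adjusted p = 0.15) except without vehicle 1 (0.0088) or CCl4 4 (0.034) and with no filter on low counts.

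Alternative activation and complement genes split. Of 16 alternative activation genes 3 rose and 5 fell (4 and 7 adjusted over the list alone), with Arg1 and Chil3 higher and Ccl24 and Cd163 lower. Of 13 complement genes 2 rose and 5 fell (2 and 7 adjusted over the list alone). C3 rose from 49.3 ± 12.1 to 252.3 ± 103.2 CPM and its receptor C3ar1 from 263.2 ± 32.7 to 607.6 ± 63.6 CPM, and properdin (Cfp) fell from 3968 ± 513 to 1189 ± 283 CPM and C6 from 634.4 ± 171.7 to 162.4 ± 34.2 CPM. Of 11 genes of MHC class II presentation 1 rose, Ctss, and 0 fell (1 and 0 adjusted over the list alone), and the median of 0.02 was -0.11 with library size only, -0.08 with upper-quartile scaling and below 0 in some other settings. Camera adjusted p was 0.48, 0.063 and 0.81 for these lists, and the complement set passed without vehicle 2 (0.027) or CCl4 3 (0.013) and in 6 other settings.

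Some cell cycle and dissociation genes fell. Of 30 cell cycle genes 6 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.52), among them Mcm5 (-1.03, SE 0.21). Of the other 5, Cdk1, Mcm2 and Tyms lost their calls without CCl4 1 (edgeR adjusted p of 0.067, 0.089 and 0.11) and without vehicle 3 (0.054, 0.087 and 0.063). Cdk1 also lost it without CCl4 3 (0.061), Mcm2 without vehicle 1 or 4 or CCl4 4 (0.069, 0.076 and 0.068) and Tyms without vehicle 1 or CCl4 3 (0.055 and 0.075). Mki67 was at 29.6 ± 3.2 and 27.4 ± 8.1 CPM (edgeR adjusted p = 0.784). The set passed camera with the preset correlation (adjusted p = 4.1e-05), with adjusted p = 0.7 with an estimated correlation and 0.13 by fry. Of 23 genes induced by tissue dissociation 6 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.51), with Ier2 (-1.51, SE 0.17), Klf2 (-2.17, SE 0.24), Dnajb1 (-1.65, SE 0.27) and Egr1 (-1.50, SE 0.26) lower. Camera gave adjusted p = 4.1e-05 with the preset correlation, adjusted p = 0.48 with an estimated correlation, and fry 0.014. These genes mark the handling of the cells, and they were lower in the same libraries as the inflammatory genes above.

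Genes of other cell types moved with the groups as well. Of 19 sinusoidal endothelial genes 13 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.05), with Clec4g (-1.65, SE 0.21), Ptprb (-1.54, SE 0.22) and Cdh5 lower and Fcgr2b higher (1.54, SE 0.18). Of these 19 genes, 7 are in another list too. Camera gave adjusted p = 1.1e-07 with the preset correlation, adjusted p = 0.42 with an estimated correlation, and fry 0.0094. Of 22 stellate cell and fibroblast genes 6 rose and 5 fell (8 and 6 adjusted over the list alone). Col1a1, the main fibrillar collagen, rose from 4.94 ± 2.31 to 28.7 ± 11.3 CPM (2.54, SE 0.36) and Hgf from 12.7 ± 1.9 to 31.9 ± 0.8 CPM, and Rgs5 (-2.64, SE 0.34) and Colec11 (-3.01, SE 0.46) fell. The stellate list's median (-0.06) and mean (0.11) differed in sign, with camera up (adjusted p = 0.55). Of 16 neutrophil genes 9 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.66), with Mmp8 (2.46, SE 0.25), Mpo (5.14, SE 0.52) and Ltf (2.76, SE 0.55) higher. Elane, a granule protease, was at 0 in all vehicle libraries and at 4.29 ± 2.03 CPM in CCl4, with counts pooled over the CCl4 libraries at least 143-fold higher per library size than a floor of 3 counts over the vehicle group, and the median with this bound was also 1.66. Camera gave adjusted p = 1.1e-07 with the preset correlation, adjusted p = 0.42 with an estimated correlation, and fry 0.0094.

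Epithelial and lymphoid lists showed few calls. Of 23 hepatocyte genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.13). Alb went from 51.1 ± 2.8 to 29.6 ± 9.4 CPM (edgeR adjusted p = 0.0314), a call that ended without vehicle 1, 3 or 4 (0.057, 0.074 and 0.082) or CCl4 1 or 2 (0.065 and 0.057), and Pck1 fell by 1.54 (SE 0.29) on the log2 scale. The third, Mup3 (-1.65, SE 0.43), lost its call without vehicle 3 or 4 or CCl4 3 (edgeR adjusted p of 0.071, 0.078 and 0.071), so 1 of the 3 was left without vehicle 3 or 4. The hepatocyte set passed without vehicle 1 (0.0088) or CCl4 3 (0.016) and in 2 other settings. Of 11 cholangiocyte genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), Spp1, Krt7 (1.39, SE 0.32) and Krt19 (2.76, SE 0.76). Spp1 is also in the scar-associated list, and at 96.2 and 2200 CPM it was far above the next member, Cd24a, at 8.39 and 17.4 CPM. The set passed camera (adjusted p = 0.0092 with the preset correlation, adjusted p = 0.7 with an estimated correlation) but not without vehicle 3 (0.13) and not by fry (0.16), and the Krt19 call ended without vehicle 1 or 2 (edgeR adjusted p of 0.081 and 0.056) or CCl4 1 or 3 (0.055 and 0.1). Of 17 B and plasma cell genes 1 rose and 2 fell (1 and 2 adjusted over the list alone): the IgG1 constant region Ighg1 rose from 0.18 ± 0.13 to 17.9 ± 17.7 CPM and Bank1 fell from 152.3 ± 17.8 to 53.1 ± 12.2 CPM. The call of Cd79b (-0.60) ended without vehicle 1, 3 or 4 (edgeR adjusted p of 0.1, 0.1 and 0.11) or CCl4 1, 3 or 4 (0.093, 0.097 and 0.085), and the median (-0.21) and mean (0.24) differed in sign. Of 19 dendritic cell genes 1 rose, Flt3 (1.13, SE 0.20), and 2 fell, Batf3 (-1.26, SE 0.19) and Clec9a (-0.73), whose call ended without any 1 library but CCl4 1 (edgeR adjusted p of 0.062 to 0.13) (1 and 2 adjusted over the list alone).

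The remaining lists had at most 2 calls each, and the genes named for them, like Cox5a, Asns, Herpud1, Zc3h12a and Ctss above, were chosen after their values were seen. Of 18 T cell genes 1 rose, Il7r (3.90, SE 0.35), and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.13 that was -0.01 with library size only and -0.06 without vehicle 3. Of 11 NK cell and ILC1 genes 1 fell, Klrk1 (-1.41, SE 0.18), and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.04 that ranged from -0.41 to 0.18 over the settings. Of 7 eosinophil, basophil and mast cell genes Siglecf rose (3.39, SE 0.48) and Ccr3 fell (-1.84, SE 0.25), with 1 and 1 also adjusted over the list alone, and the median (-0.31) and mean (0.28) differed in sign. Of 9 erythroid and platelet genes 1 fell, Pf4 (-1.30, SE 0.37), and 0 rose (1 and 0 adjusted over the list alone), with a median of 0.06, a mean of -0.09, and a median of -0.17 with library size only, -0.12 with upper-quartile scaling and of either sign on leaving out 1 library. Of 2 tested sex-linked genes 0 passed (0 adjusted over the list alone). Camera adjusted p was between 0.55 and 0.92 for the T cell, NK cell, eosinophil, erythroid, B cell and dendritic cell sets.

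Across the 38 sets tested, 16 passed camera with the preset correlation and 0 with an estimated correlation, for which the smallest adjusted p was 0.42 and 4 sets had an unadjusted p under 0.05. By fry 13 sets passed, 12 of them among the 16.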

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

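Of the tests in this part, those on other splits of the libraries and the one on the further stellate gene lists were set before their results were seen, and the others were chosen after. A library far from the other 3 of its group was found in 15 of 316 groups of values (4.7%), and chance alone gives about 1 in 20. In CCl4 3, C3 was at 407.1 CPM (the others 199.2 to 203.3), Fcgr2b at 397 (285.9 to 296.6), Krt19 at 12.58 (4.07 to 4.614) and Upk3b, a uroplakin of the mesothelium, at 45.99 (12.7 to 14.11). CCl4 2 held Cdk1 at 16.13 CPM (8.51 to 9.112), Mcm5 at 17.11 (10.28 to 10.82), Ly6c2 at 5.954 (1.711 to 2.188) and a summed B and plasma cell list of 867.28 (381.97 to 461.96). In CCl4 1, Ccl9 was at 428.8 CPM (255.4 to 277) and the summed T cell list at 169.04 (151.44 to 152.39). CCl4 4 held Fcna at 627.7 CPM (868.7 to 887.7) and Mmp8 at 17.03 (33.71 to 36.77). In vehicle 4, Cx3cr1 was at 161.2 CPM (107.7 to 111.5), Itgam at 201.4 (79.79 to 80.37) and Slc16a3 at 40.45 (10.22 to 14.56). Itgam, an integrin of recruited myeloid cells, passed the edgeR test without vehicle 4 (log2 fold change 1.35, adjusted p = 0.00042) and not with it (0.88, adjusted p = 0.062); it passed in 7 of 26 alternatives, with adjusted p from 0.00042 to 0.21.

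The 2311 genes called between CCl4 and vehicle stand against a highest count of 0 in the other splits of the 8 libraries. So 1 of 35 splits, the real one, gave as many, which is the smallest share the design allows. Every other split mixes the groups, so the size of the gap says nothing more. Chance can be excluded at 0.05 only as a random labelling of these libraries. Chance differences between mice or preparations stay open, since the labels do not say that each library is a separate mouse. The same holds for the medians of the Kupffer cell list (1.49 from 0, against 0.99 in the highest other split, 1 of 35) and of the lipid and scar associated list (2.20 against 1.20, 1 of 35). It does not hold for the number of lists past camera with the preset correlation: the real split gave 16, the highest other count was 17, and 7 of 35 splits gave as many. That number alone cannot be set apart from chance. Splits that mix the groups gave from 3 to 17 lists, so a pass of a single list with the preset correlation is weak evidence by itself. Each such pass is therefore given above with its adjusted p by fry and with an estimated correlation.

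The fall of Kupffer cell genes by a median of 1.49 on the log2 scale stayed at -1.65 with the receptor gene level as a covariate. That level was 1731 ± 892 CPM in vehicle and 1321 ± 1119 CPM in CCl4 (exact permutation p = 0.486). A covariate that does not separate the groups could hardly remove their difference, so it does not decide the question. Without vehicle 2 and CCl4 4 the median was -1.46, which argues against the background reads of these libraries as the source. A few abundant genes taking more of the counts would lower all others by 1 factor. Yet the median of all tested genes with library size only was -0.155 against -1.62 for the list. A lower share of Kupffer cells in the sort, with unchanged expression in each, would lower all members by 1 factor. Their falls were unequal (Cochran's Q of 247.7 over n = 24 genes, chi-square p = 1.4e-39, SD 0.80 against a median SE of 0.23, with genes taken as independent), but other macrophages may express some members. Fewer Kupffer cells and lower expression per Kupffer cell therefore cannot be told apart in sorted bulk RNA. Both stay open as effects of the treatment.

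The fall of the 13 mitochondrially encoded genes (median -1.89) was not a shift of reads to nuclear copies of these genes, since genes and copies summed together had a log2 ratio of -1.93. The median stayed at -1.88 with the receptor gene covariate, which does not separate the groups and so could hardly remove their difference. A fall of the respiratory chain as a whole is argued against by the nuclear-encoded members, with a median of -0.12. Unequal cell damage during digestion stays open: the dissociation list fell too (median -0.51), so damage and treatment cannot be told apart. A treatment effect on mitochondrial RNA is untested beyond this and remains a hypothesis.

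Genes of stellate cells and sinusoidal endothelium were measured although the CD45 and CD31 gates would remove both cell types. Less RNA carried over from both in CCl4 cannot be told apart from a change in these cells: over members in no other list the mean log2 CPM of 12 endothelial genes went from 5.2 ± 0.37 to 4 ± 0.41 and that of 21 stellate genes from 3.34 ± 0.56 to 3.33 ± 0.24 (SD, n = 4, exact permutation p = 0.029 for the difference of the 2, the smallest possible), but the stellate genes went both ways (SD of log2 fold changes 1.58), so their mean decides nothing. The summed stellate list was at 1254 ± 465 and 818 ± 131 CPM, with no detectable difference (exact permutation p = 0.2, adjusted to 0.327 over 18 sample-level values). Its most abundant members were Ecm1 (747.1 to 467.5 CPM), Dcn (207.1 to 83.1) and Col3a1 (27.2 to 85.2), of which Dcn did not pass. In all, 1 of 22 stellate and 7 of 19 endothelial members are also in another list. A candidate explanation is that stellate RNA in the sort came from more activated and fewer quiescent cells. In 2 further lists, activation genes had a median of 0.68 (3 of 14 higher) and quiescence genes one of -1.67 (10 of 16 lower), a difference of 2.35, with unadjusted p of 0.33 and 0.14 by camera with an estimated correlation and 0.082 and 0.0059 by fry, so the activation side is weak, and expression by the macrophages themselves stays open.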

How the results depend on the processing

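Vehicle 2 and CCl4 4 left out together, the 50 most abundant genes left out, a length trend removed and the receptor gene covariate were chosen after seeing the data; all other alternatives were set before. The medians of the Kupffer cell, lipid and scar associated and monocyte lists kept their direction and their camera call with the preset correlation in all 26 alternatives. Camera was not run with an estimated correlation in the alternatives. With DESeq2 and with limma-voom, weighted or not, camera used the log2 CPM of the main fit. Its p-values there repeat the main result and add nothing to it. Of 125 named genes past the threshold, 81 stayed past it in every alternative where they were tested. Of the 44 lost at least once, 29 were lost only in the FPKM table without a filter, for which the cause was not tested, and 14 were lost on leaving out 1 library. Of 15 named genes not past it, 8 passed in some alternative. Among the 16 lists past camera with the preset correlation, 12 kept their call in all alternatives, and the cholangiocyte, inflammatory, interferon and phagocytosis lists did not. Another 7 of 22 lists passed in at least 1.

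Against 1358 higher and 953 lower genes, library size only gave 1431 lower and limma-voom with sample quality weights 1489 lower; the cause of the second was not tested. The FPKM table gave 448 higher and 543 lower on log2(FPKM + 1), 436 and 521 on log2(FPKM + 0.1), where 6359 genes were tested (839 and 825 calls shared in direction, 2 opposite in each), and 335 and 315 with no filter (595 shared). With no filter Eci1 reversed, from -0.51 to 0.02, and the median of the phagocytosis list went from 0.29 to 0; the cause was not tested. Leaving out each library in turn gave 1004 to 1503 higher genes, 578 (without CCl4 1) to 1163 lower genes, and 15 to 18 lists. In those fits the medians ran from -1.72 to -1.38 for the Kupffer cell list, 2.03 to 2.31 for the lipid and scar associated list and 1.16 to 1.84 for the monocyte list. Leaving out vehicle 2 and CCl4 4 together gave 1653 higher and 1163 lower genes, and 2059 of the 2311 calls were shared in direction. Each group has 4 libraries. In simulation, for genes above a minimum level, the test recovered 72% of changes of log2 1, so small differences can stay undetected.

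Replicate numbers 1 to 4 occur in both groups, and pairing by number was checked from the libraries' deviations from their group means. Same-numbered libraries correlated at 0.02, -0.24, 0.04 and -0.17, and no library correlated best with its own number. Pairing by number was therefore not seen. A weak pairing cannot be excluded, since libraries of unlike number correlated by as much as 0.47 (vehicle 2 with CCl4 4). The replicate number as a block gave 1281 higher and 829 lower genes, of which 1938 calls were shared, with 8 named genes lost, 3 gained and no list call changed.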

Other observations

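The genes, lists and tests of this part were chosen after the values were seen, so the p-values of its lists add no support beyond the values themselves. Genes of the mesothelium, the cell layer that covers the liver, were higher in CCl4, although the CD45 gate would remove mesothelial cells. Of 12 tested, 8 rose and 0 fell, with a median log2 fold change of 2.89. Lrrn4 had a log2 fold change of 5.96 (SE 0.66), Upk1b one of 4.65 (SE 0.59), Upk3b one of 3.98 (SE 0.64), Msln one of 3.80 (SE 0.62) and Gpm6a one of 3.03 (SE 0.25). Levels were low, with Upk3b at 1.35 ± 1.13 CPM in vehicle and 21.7 ± 16.2 CPM in CCl4 and Lrrn4 at 0.13 CPM in vehicle. The unadjusted p of the set was 0.034 by camera with an estimated correlation and 0.00026 by fry. Keratins Krt8, Krt18 and Krt19 are in this list and in the cholangiocyte list.

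Genes shared by osteoclasts and by the Mitf and Tfe family of lysosome regulators were higher on balance as well. Of 18 tested, 11 rose and 1 fell (median 0.98). The proton pump subunit Atp6v0d2 had a log2 fold change of 6.34 (SE 0.36), the collagen-degrading cathepsin Ctsk one of 4.05 (SE 0.53), the cell fusion protein Dcstamp one of 3.47 (SE 0.68), Atp6v0a1 one of 1.80 (SE 0.26) and Mitf itself one of 0.88 (SE 0.20). Tfec fell (-0.79, SE 0.13), while Tfeb (0.23, SE 0.16) and Tfe3 (0.19, SE 0.22) did not pass. Nor did the osteoclast genes Acp5 (0.42, SE 0.17), Nfatc1 (0.56, SE 0.22) and Ocstamp (0.88, SE 0.38), or the pump subunit Atp6v1b2 (0.30, SE 0.19). The unadjusted p was 0.039 by camera with an estimated correlation and 0.00017 by fry, for a list chosen after these values were seen. Its members Ctsd and Psap are in the lysosome list too, Atp6v0d2 and Ctsd are in the lipid and scar associated list, and Acp5 and Atp6v1a are in fixed lists as well. The rise of this list is therefore not separate from the rises given above.

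Among 8 tested immunoglobulin constant region and J chain genes, the IgG genes Ighg1 (6.63, SE 0.82) and Ighg2b (4.79, SE 0.96) rose, and Ighm (0.76, SE 0.43) and Igkc (0.55, SE 0.45) did not pass. Ighg1 was at 9.90, 44.1, 12.2 and 5.28 CPM in CCl4 1 to 4 and at most 0.32 CPM in any vehicle library. The B cell gene Ms4a1 did not pass. Reads can be shared among immunoglobulin genes, so these values are uncertain. Of 18 collagen and quiescence genes of stellate cells 8 rose and 5 fell, with an unadjusted camera p of 0.53 with an estimated correlation.

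Olfactory and vomeronasal receptor genes, 1465 in all, summed to 3029 CPM in vehicle 2 and 2979 CPM in CCl4 4 against 598 to 1509 CPM in the other libraries, spread over many genes, with 11.7% of their counts from the most abundant one. The Y-linked genes Ddx3y and Eif2s3y were at or below 0.918 CPM in all 8 libraries. Of the sex-linked genes that were tested, Kdm5d was at 7.15 ± 3.83 CPM in vehicle and 7.61 ± 6.43 CPM in CCl4. Uty was at 1.11 ± 0.59 and 1.07 ± 1.10 CPM (edgeR adjusted p = 0.934 for Kdm5d and 0.976 for Uty).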
